A study of Mus musculus with 2 samples.

How the data were processed

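Single-cell RNA sequencing libraries were made from injured kidneys of mice after unilateral ischaemia/reperfusion injury, 1 library from the group with contralateral nephrectomy and 1 from the group with the contralateral kidney intact. Per the labels' protocols, the kidneys were minced into pieces of 1 mm3 and digested for 25 min at 37 °C with the enzymes Liberase, at 100 µg/mL, and DNase I, at 10 µg/mL. They were then passed through 40-µm strainers, and used when viability by trypan blue was above 70%. The submitters' processing notes name Cell Ranger 3.0.0, Seurat 3.1.0 and the mouse genome build mm9; the steps in which each was used are not given in the sources used here. No genome coordinates were used.

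The deposited expression table holds, for 14648 genes and 5634 cells, the natural log of 1 plus a whole number; exponentiating it gave whole numbers within 0.001 for 100% of the values. These numbers are depth-corrected counts and not raw molecule counts, since their totals lay between 836 and 1976 in every cell, a span of 2.36-fold. A depth index, described below, varied far more between cells. A deposited second table, recorded as a score, holds the same corrected counts; it stops within a line after 8666 whole genes, showed no difference from the first table there, and was not used further. A deposited residual table, also recorded as a score, holds values from -8.88 to 15.0 for 3000 genes; it served as an alternative basis for clustering and for the depth index. How the authors corrected for depth and which cells they removed is not given in the sources used here, and cell types were assigned from markers. All cells were used and no column was left out.

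Because the plan had been written for raw molecule counts, its counting intervals for expression ratios were not computed, and genes were ranked by the size of the log2 ratio instead. Shares of cells keep exact Clopper-Pearson 95% intervals. The markers, the gene lists, the naming rule, the random lists and 26 alternatives were fixed before the data were examined; 17 more alternatives, the depth index and the handling of haemoglobin-marked clusters were added after the data had been seen. With 1 library per group there was no test between groups.

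A depth index was computed for each cell from the residuals of zero values in 1653 rare genes (found in at most 60 cells), which in the deposited table grow more negative with depth, and was scaled to a median of 1. Indices from alternating, non-overlapping sets of these genes had a Spearman correlation of 0.994, and the index had one of 0.791 with the corrected total. Its 5th and 95th percentiles were 0.134 and 10.3, and its medians were 1.01 with nephrectomy and 0.984 with the other kidney intact. Equal corrected totals therefore hide wide differences in true depth between cells and classes, and the absence of a gene in a shallow cell carries little weight.

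For clustering, corrected counts were scaled to 10000 per cell and taken as ln(1+x), 2000 highly variable genes were scaled with a cap of 10, and 30 principal components, 15 neighbours and Leiden clustering at a resolution of 1.0 (seed 0) gave 25 clusters, without batch centring. Clusters were named from 23 fixed marker sets by the markers detected and by those among the 10 genes with the highest fold over the other cells, and the suffix -like is used since only transcripts define them. Clusters whose only leading markers were haemoglobin genes or that met no marker set clearly were left unnamed. Doublet scoring with scrublet, run through scanpy, marked 1 and 3 cells (0.0710% of all), too few for this method to have worked on depth-corrected values, so no doublets were removed and doublets must be taken to be present.

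Within a class with at least 50 cells in each library, corrected counts were summed per library and expressed as CPM. The log2 ratio was taken as intact over nephrectomy with 5 CPM added to each. Genes were named when their sum reached 50, the higher library reached 100 CPM and the ratio reached 2; the 12 largest each way were taken in proximal tubule-like and macrophage-like cells and the 5 largest each way elsewhere. Left out were markers of another class, genes over 5 times as high in another class (free RNA released by other cells), and mitochondrial, ribosomal, haemoglobin, unnamed and sex-linked genes. From each of 25 gene lists the 4 most abundant members and those differing by at least 2-fold could be named too. A few genes that meet these rules are not reported here. A list member was measured with at least 20 corrected counts over both libraries, and was called higher or lower at a ratio of at least 1.5, otherwise between. The median log2 ratio of the measured members was placed among the medians of 10000 random lists of equal size, matched in 20 bins of expression, and was called outside the random range below the 2.5th or above the 97.5th percentile. Shares of cells with a value of a gene were taken after thinning each cell to 1000 corrected counts, and a share of 0 is given with a floor of 3 cells of the total.

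The naming rule and the list comparison were tested on simulated data drawn at the totals of the classes. Only genes that reached the sum and CPM the rule needs were scored, so planted genes under these levels do not enter the rates. The cut to the largest genes and the genes left out of naming were not simulated. Scored genes planted at a 4-fold difference all met the ratio of 2. They were 43 higher and 14 lower in proximal tubule-like cells and 50 and 23 in macrophage-like cells. At 2-fold, 50.0% (of 28) and 37.0% (of 46) of those planted as higher met it. Of those planted as lower, 71.4% (of 7) and 61.3% (of 31) did. Of unchanged genes at these levels 0% (of 1193) and 0.263% (of 760) met it, and 95.5% and 95.7% of unchanged lists lay within the random range. The simulated sums held counting error alone, drawn from the pooled profile of each class. Variation between cells, free RNA and animals was not simulated, so these rates need not hold for the real libraries. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.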

Results

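The series profiled single cells of mouse kidneys after ischaemia/reperfusion injury (IRI), in which the blood supply of a kidney is stopped for a time and then restored. Both libraries were made from injured kidneys of wild-type C57BL/6 mice 11 weeks old. In 1 group the opposite, uninjured kidney had been taken out (contralateral nephrectomy, a library titled Repair). In the other group it stayed in place (contralateral kidney intact, a library titled Atrophy). The title of the series asks how an injured kidney repairs itself and how a faulty repair ends in the loss of kidney mass. Each group held 1 library, so no difference reported here has a replicate check and no p-value is given. Each comparison is of 2 libraries, not of 2 conditions. The time between injury and harvest is not given in the sources used here.

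The nephrectomy library held 3594 cells and the intact library 2040 cells, with values for 14648 genes. The deposited values are depth-corrected counts and not raw molecule counts, so the true depth of a cell is unknown. The corrected counts summed to a median of 1268 per cell (quartiles 1114 and 1472) with nephrectomy and 1217 (quartiles 1094 and 1457) with the other kidney intact. A median of 514.5 and 479 genes per cell had a value. Genes encoded by the mitochondrial genome took a median of 20.3% of the corrected counts of a cell with nephrectomy and 13.7% with the other kidney intact. Values are given in the order nephrectomy, intact throughout. Levels are corrected counts of a gene scaled to a common class total (CPM).

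Leukocytes took a larger share, and proximal tubule-like cells a smaller share, of the intact library than of the nephrectomy library. Proximal tubule-like cells, the epithelium that takes back most of the filtrate, were 1548 of 3594 cells (43.1%, 95% interval 41.4 to 44.7) and 370 of 2040 cells (18.1%, 16.5 to 19.9). The leukocyte classes together were 666 cells (18.5%, 17.3 to 19.8) and 926 cells (45.4%, 43.2 to 47.6). These totals leave out the unnamed clusters 10, 12 and 17, which held leukocyte genes, and with them the shares were 25.4% and 54.7%. T-like cells differed by the largest factor among the named classes, with 94 cells (2.62%, 2.12 to 3.19) and 252 cells (12.4%, 11.0 to 13.9), a share 4.72-fold higher in the intact library. Injured tubule epithelium-like cells, in which Havcr1 (kidney injury molecule 1) and Spp1 (osteopontin) were among the leading genes, were 132 cells (3.67%, 3.08 to 4.34) and 145 cells (7.11%, 6.03 to 8.31). All intervals are exact Clopper-Pearson intervals and cover counting error only, not the spread between animals.

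Among the other immune classes, macrophage-like cells were 441 cells (12.3%, 11.2 to 13.4) and 476 cells (23.3%, 21.5 to 25.2), a ratio of 1.90. Natural killer (NK)-like cells were 29 and 65 cells (0.807% and 3.19%, ratio 3.95) and neutrophil-like cells 52 and 83 cells (1.45% and 4.07%, ratio 2.81). Dendritic-like cells, led by Xcr1 and Clec9a, were 14 and 23 cells (0.390% and 1.13%, ratio 2.89). B-like cells were 36 and 27 cells (1.00%, 0.703 to 1.38, and 1.32%, 0.874 to 1.92), a difference within the counting error. Endothelial-like cells were 165 and 114 cells (4.59%, 3.93 to 5.33, and 5.59%, 4.63 to 6.68). Stromal-like cells with collagen genes were 29 and 23 cells, both classes with overlapping intervals. Cells of the thick ascending limb, which also held genes of the distal convoluted tubule, were 142 and 39 cells (3.95% and 1.91%, ratio 0.484). Intercalated-like cells were 29 and 10 cells. Proliferating-like cells, led by Birc5, Ube2c and Top2a, were 40 and 35 cells (1.11%, 0.796 to 1.51, and 1.72%, 1.20 to 2.38).

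The 5 clusters that stayed unnamed held 843 cells (23.5%) and 378 cells (18.5%). The largest, cluster 0, held 541 and 109 shallow cells (15.1% and 5.34%) led by tubule genes such as Acy3 and Akr1c21, with 3 detected proximal tubule markers and none of them among its 10 leading genes. Clusters 10 (5.34% and 4.07%) and 19 (1.56% and 3.87%) had haemoglobin genes as the only markers among their leading genes and were kept out of the classes after the data had been seen, since haemoglobin RNA was found in each class compared. Cluster 10 also held leukocyte transcripts, with Cd74 at 18250 and 15710 CPM in 191 of 192 and 83 of 83 cells. Unlike in macrophage-like cells, Ccl8 (389 and 149.8 CPM) and Ccl7 (176 and 21.4 CPM, on 38 and 2 corrected counts) were lower in it in the intact library. Cluster 12, led by Ccl22, Fscn1 and Il12b, held 16 and 28 cells, and cluster 17, led by Ear2, Cd209a and Retnla, 38 and 79 cells, of which a clustering at a higher resolution set 16 and 15 apart as monocyte-like. Enzymatic digestion and a 40-µm strainer set which cells were recovered, and the composition of the tissue itself was not measured. Within leukocytes alone the macrophage-like ratio turned to 0.776 and those of T-like, NK-like and neutrophil-like cells were 1.93, 1.61 and 1.15. The highest marker score in place of clusters gave 2.06 for NK-like and 1.71 for neutrophil-like cells. The injured tubule ratio was 1.06 among cells with a depth index (a relative measure of the depth of a cell, with a median of 1) of at least 1 and 1.21 among cells with at least 1000 corrected counts and under 25% mitochondrial counts. The T-like ratio was 2.51 among cells with an index under 1.

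**Figure D1:**
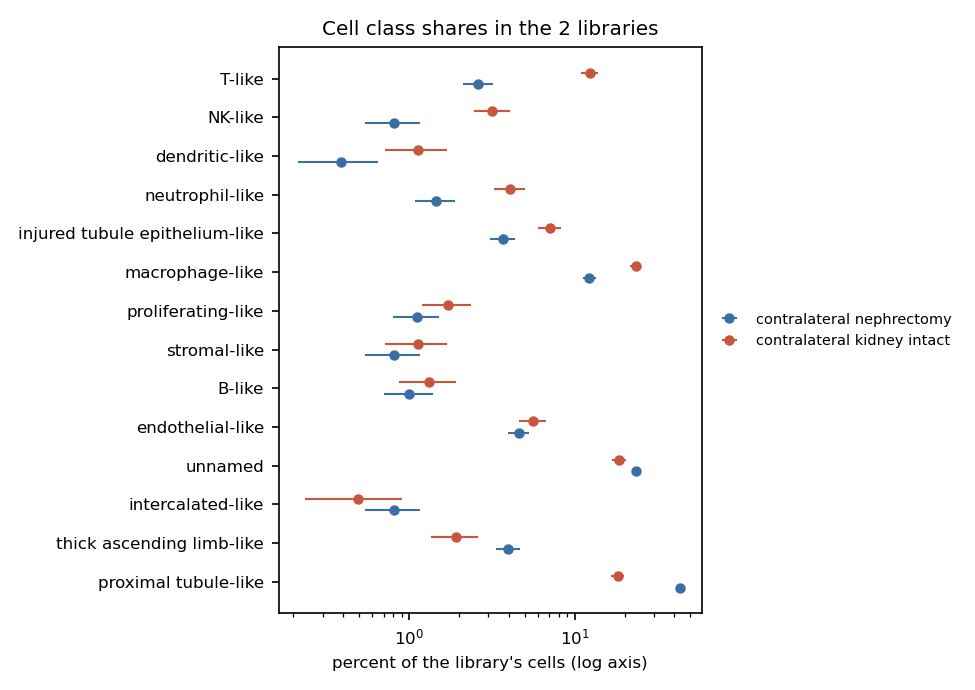
Share of each cell class in percent of the cells of its library (log axis), in the nephrectomy library (blue) and the intact library (red), with exact 95% binomial intervals as bars. T-like cells were at 2.62% and 12.4%, and proximal tubule-like cells at 43.1% and 18.1%.

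Over proximal tubule-like cells as a class, transporters and genes under androgen or estrogen control stood higher in the intact library. Genes of fatty acid oxidation and of peroxisomes and redox control stood lower in it. The single clusters of the class did not all follow. Dnase1, which encodes a secreted endonuclease, was at 162 and 582 CPM, 3.59-fold higher in the intact library. Gsta2, a glutathione transferase, was at 834 and 235 CPM, 3.55-fold lower. Pck1, the rate-limiting enzyme of gluconeogenesis, was at 1652 and 669 CPM, 2.47-fold lower. Dnase1 was higher, and Gsta2, Pck1, Acaa1b, Bnip3, Ak4 and Pxmp4 were lower, in the intact library within each of the 6 clusters of the class. The clusters held unlike parts of the class: cluster 7, led by Slc7a13, Kap and Slco1a1, genes of the straight segment of the proximal tubule, held 22.6% and 48.4% of it, and cluster 5, led by Amacr, Mpv17l and Aadat, 24.6% and 6.22%.

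The 12 genes named as higher in the intact library by the rule of size included several of lipid handling: Lpl, lipoprotein lipase (129 and 416 CPM), Cd36, a fatty acid receptor (96.7 and 296 CPM), and Apom, an apolipoprotein (46.8 and 132 CPM). Slco1a1, an organic anion transporter, was at 96.3 and 339 CPM in the class and at 248 and 591 CPM within cluster 7, which it helps to define. Lpl was at 331 and 703 CPM and Cd36 at 263 and 483 CPM within that cluster, where most of their counts lay. In cluster 1 Lpl was at 35.7 and 28.6 CPM, and in cluster 5 it was at 28.5 and 29.7 CPM and Cd36 at 40.9 and 29.7 CPM. These intact levels rest on 1 or 2 corrected counts, and neither gene was higher in each cluster. Drug and steroid metabolism was represented by Ugt2b38 (300 and 708 CPM), Ugt2b37 (129 and 304 CPM), Por, the reductase that serves cytochromes P450 (55.9 and 152 CPM), and Hsd17b11 (37.6 and 105 CPM). Serpinf2, the main inhibitor of plasmin (72.0 and 187 CPM), Tspan3 (67.8 and 156 CPM) and Car4, a membrane-bound carbonic anhydrase (87.6 and 199 CPM), completed the group. Among the 12 named as lower, the thiolases Acaa1b (632 and 251 CPM) and Acaa2 (227 and 109 CPM) and the peroxisomal membrane protein Pxmp4 (234 and 112 CPM) belong to fatty acid breakdown or its organelles. Bnip3, a mitophagy receptor (268 and 112 CPM), Ak4, a mitochondrial adenylate kinase (267 and 112 CPM), and Sdhaf4, an assembly factor of succinate dehydrogenase (140 and 61.2 CPM), serve mitochondria. Gstp1 (446 and 201 CPM), Sms, spermine synthase (120 and 49.3 CPM), Otub1, a deubiquitinase (106 and 49.3 CPM), and Trappc4 (103 and 47.3 CPM) were the others. Levels of genes with near-identical copies, among them Acaa1b, Gsta2, Gstp1, Ugt2b37 and Ugt2b38, are uncertain where reads could be split between copies.

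**Figure D2:**
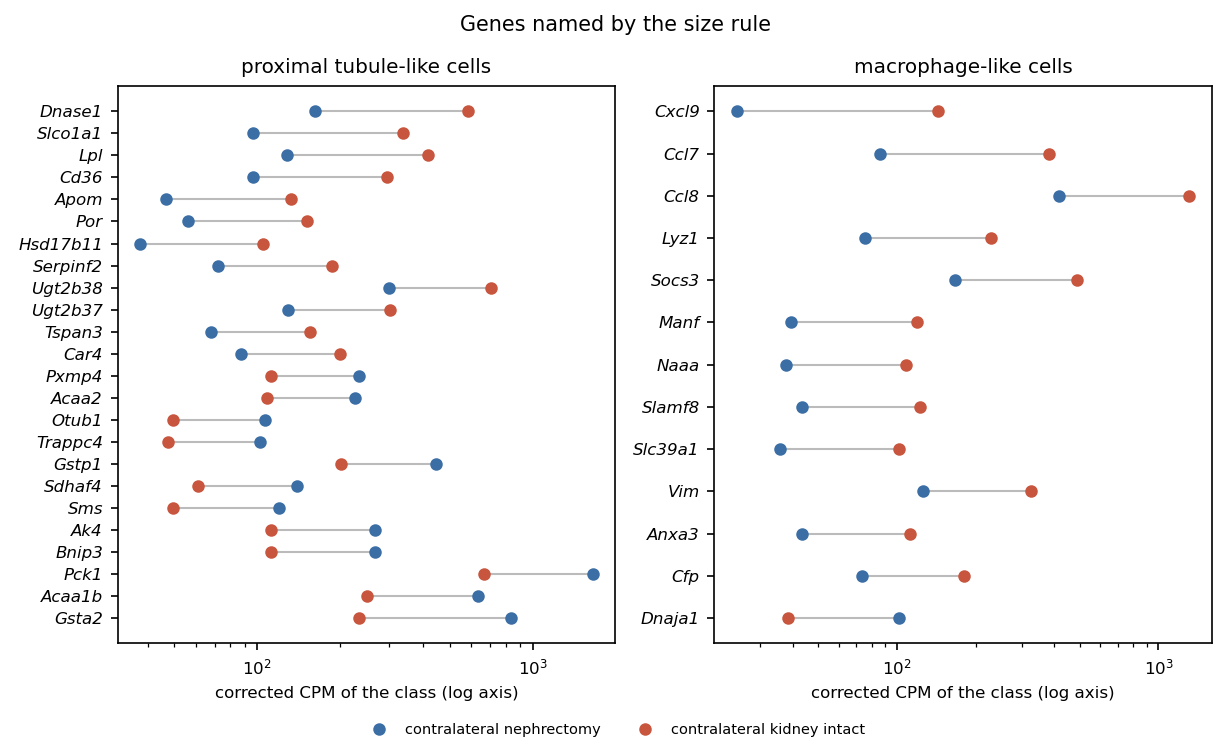
Levels of genes named by the rule of size, in corrected CPM of the class (log axis), in the nephrectomy library (blue) and the intact library (red), for proximal tubule-like and macrophage-like cells. Dnase1 was at 162 and 582 CPM in proximal tubule-like cells, and Ccl8 at 415 and 1313 CPM in macrophage-like cells.

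Of 23 proximal tubule transporters measured, 9 were at least 1.5-fold higher, 1 was lower and 13 lay between. The median log2 ratio was 0.47, at the 100th percentile of 10000 random lists matched on expression. Slc34a1, the main phosphate transporter, was at 1097 and 2012 CPM, Slc27a2 at 638 and 1162 CPM, Slc7a13 at 139 and 310 CPM, and the endocytic receptor Lrp2 at 569 and 635 CPM. With each cluster weighing alike the median was 0.15, inside the range of random lists. In cluster 1, where 19 were measured, none was higher, 5 were lower and the median was -0.21. Of 12 measured genes under androgen or estrogen control, 9 were higher, 2 were lower and 1 lay between, with a median of 0.97 (100th percentile). Kap, kidney androgen-regulated protein, was at 16563 and 30134 CPM, Cyp4b1 at 659 and 1375 CPM, and Cyp4a12a at 7.79 and 53.3 CPM, while Cyp4a14 was at 55.5 and 3.95 CPM. Within cluster 7 Kap was at 42780 and 51340 CPM. It was also higher in clusters 3, 5 and 8 of the intact library but lower in clusters 1 and 2. Cyp4b1 was at 1275 and 2108 CPM in cluster 7 and at 1496 and 1566 CPM in cluster 8. It was higher in clusters 1, 3 and 5 too and lower in cluster 2. The median of the androgen or estrogen list was 0.42 with each cluster weighing alike. It lay between 0.45 and 0.56 in clusters 5, 7 and 8 and between -0.14 and 0.29 in clusters 1, 2 and 3. Only in clusters 5 and 7 was it above the random range. The sex of the mice is not given in the sources used here, and the list shares Slc7a13 and Slc22a30 with the transporters. It mixes genes under androgen control with genes under estrogen control, so its median does not measure androgen control.

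Of 26 fatty acid oxidation genes measured, 1 was higher, 7 were lower and 18 lay between, with a median of -0.33 (0.680th percentile) that was -0.23 with each cluster weighing alike (0.0600th percentile, below the random range). Within single clusters it was -0.68 in cluster 8, below the random range, between -0.27 and -0.10 in clusters 1, 2, 3 and 5 and 0.16 in cluster 7, inside it in these 5. Acadm, the medium-chain acyl-CoA dehydrogenase, was at 571 and 426 CPM and Etfb at 976 and 817 CPM. Acsm2, a medium-chain acyl-CoA synthetase, was at 861 and 1314 CPM. Of 17 peroxisome and redox genes, 5 were lower, none was higher and 12 lay between (median -0.37, 0.120th percentile). With each cluster weighing alike the median was -0.13, at the edge of the random range, and it lay below that range in clusters 3 and 5 (-0.26 and -0.35) and was 0.07 and 0.14 in clusters 2 and 8. Nqo1, an oxidoreductase, was at 61.0 and 29.6 CPM and Prdx1 at 2949 and 2275 CPM, while Gpx3, the secreted glutathione peroxidase, was at 17399 and 19530 CPM. Of 14 genes of glycolysis and gluconeogenesis, 1 was higher, 1 was lower (Pck1) and 12 lay between, with a median of -0.32 (2.05th percentile). Within the 6 clusters the median lay between -0.12 and 0.19, inside the random range in each. Fbp1, a gluconeogenic phosphatase, was at 1292 and 961 CPM and Gapdh at 2511 and 2235 CPM. None of the 32 nuclear genes of oxidative phosphorylation differed by 1.5-fold (median -0.15, inside the random range). The 13 mitochondrially encoded genes had a median of 0.10 (98.0th percentile) over the class, but -0.28 with each cluster weighing alike and between -0.41 and -0.15 in each of the 6 clusters. mt-Co3 was at 43356 and 44188 CPM.

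Genes of tubule injury, over the class as a whole, and genes of immune cells stood higher in the proximal tubule-like cells of the intact library, most at levels under 100 CPM. Of 12 tubule injury genes measured, 7 were higher, 2 were lower and 3 lay between (median 0.68, above the random range). Vcam1 was at 5.04 and 21.7 CPM, S100a6 at 16.96 and 49.3 CPM and Spp1 at 541 and 813 CPM, while Prom1 was at 19.7 and 5.92 CPM. Over the members with at least 100 corrected counts the median was 0.09, and with a depth index of at least 1 it was 0.21. Within single clusters, on 3 to 8 measured members, it lay above the random range in cluster 3 (0.78). It lay inside that range in clusters 1, 2, 5 and 7 (0.15, 0.82, 0.35 and 0.09). All 6 measured genes of antigen presentation by major histocompatibility complex (MHC) class II were higher, with a median of 1.53 (100th percentile): Cd74, the invariant chain, was at 234 and 760 CPM and H2-Ab1 at 83.4 and 276 CPM. All 8 measured MHC class I genes were higher too (median 1.47), with B2m at 142 and 379 CPM. Macrophage genes stood higher beside them: 7 of 9 of the resident kidney macrophage list were higher and 1 was lower (median 1.05), with C1qa at 26.1 and 65.1 CPM and Apoe at 158 and 472 CPM. In T-like cells, which do not use Cd74 for presentation in the mouse, it was at 712 and 740 CPM, and in endothelial-like cells at 812 and 1162 CPM. The proximal tubule-like level thus lay below this background with nephrectomy and within it with the other kidney intact.

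Several further lists stood above the random range in proximal tubule-like cells, on few and low members. Some share members, such as Il1b and Cxcl10, and are not independent. All 8 measured complement genes (median 1.27) and all 6 inflammatory macrophage genes (1.07) were higher, among them Cfb at 33.0 and 94.7 CPM and Il1b at 7.79 and 29.6 CPM. Of 11 chemokines and cytokines 8 were higher and 3 lay between (0.81), and of 6 NF-kB response genes 4 were higher and 2 lay between (0.80). Of 4 interferon response genes 3 were higher and 1 lay between (1.88). Cxcl10, a chemokine that draws T cells, was at 3.67 and 41.4 CPM, and Mif, the cytokine with the highest level here, at 1205 and 894 CPM. Reparative macrophage genes (4 of 6 higher, 1 lower, 0.62), matrix and fibrosis genes (5 of 8 higher, 3 between, 0.69) and endothelial activation genes (3 of 3, 0.95) lay above it as well. Timp3, an inhibitor of matrix proteases, was at 529 and 744 CPM and Igfbp7 at 481 and 935 CPM. Of 16 dissociation stress genes 7 were higher and 9 lay between (0.27, 99.2th percentile), with Junb at 31.2 and 98.6 CPM, but the median was -0.01 over members with at least 100 corrected counts. Cell death (1 of 10 higher, 2 lower, -0.25), senescence (1 of 8 higher, 1 lower, -0.23), proliferation (2 of 7 higher, 1 lower, -0.15) and haemoglobin genes (1 of 4 higher, 0.35) lay inside the random range.

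The shares of proximal tubule-like cells with a value of 12 injury and signalling genes were taken after each cell had been thinned to 1000 corrected counts, which left out 12 and 7 shallower cells. Havcr1 had a value in 0.326% (0.106 to 0.758) and 0.551% (0.0668 to 1.98) of the cells, and Vcam1 in 0.326% and 1.65% (0.609 to 3.56). Cxcl2 had one in 0.521% and 1.93%, Il34, a ligand of the macrophage growth factor receptor, in 1.497% and 1.93%, and C3 in 1.04% and 2.20%, all with overlapping intervals. With fewer counts kept per cell, the shares with Cxcl2 were 0.194% and 0.270%. Unthinned, these shares were 0.517% and 0.811% for Havcr1, 0.711% and 2.43% for Vcam1, 0.646% and 2.43% for Cxcl2, 2.20% and 1.89% for Il34 and 1.49% and 2.43% for C3. Lcn2 had a value in 0.391% and in 0 of 363 cells, where a floor of 3 cells allows a share of up to 0.826% of cells with a value, not of cells that express the gene. Ccl2 (0.130% and 0.275%), Cxcl1 (0.391% and 0.275%), Krt20 (0.0651% and 0.275%) and Csf1 (0 of 1536 and 0 of 363 cells, by the same floor up to 0.195% and 0.826%) were near the level of single cells. Unthinned, they were 0.129% and 1.08% for Ccl2 (2 and 4 cells), 0.646% and 0.270% for Cxcl1 and 0.0646% and 0.270% for Krt20. Csf1 had a value in 1 and Lcn2 in 7 of 1548 cells, and both in 0 of 370, which allows up to 0.811%. Spp1 had a value in 20.3% (18.3 to 22.4) and 23.97% (19.7 to 28.7; unthinned 24.4% and 30.3%), against 10.1% and 12.7% of T-like cells and 8.33% and 15.1% of endothelial-like cells. Cd74 had a value in 16.02% (14.2 to 18.0) and 39.9% (34.9 to 45.2; unthinned 20.5% and 45.9%), against 34.8% and 33.9% of T-like and 29.5% and 46.2% of endothelial-like cells. The intact share lay between those of these background classes. The median depth index was 2.79 and 1.86 in proximal tubule-like, 1.92 and 3.34 in T-like and 1.02 and 1.40 in endothelial-like cells.

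**Figure D3:**
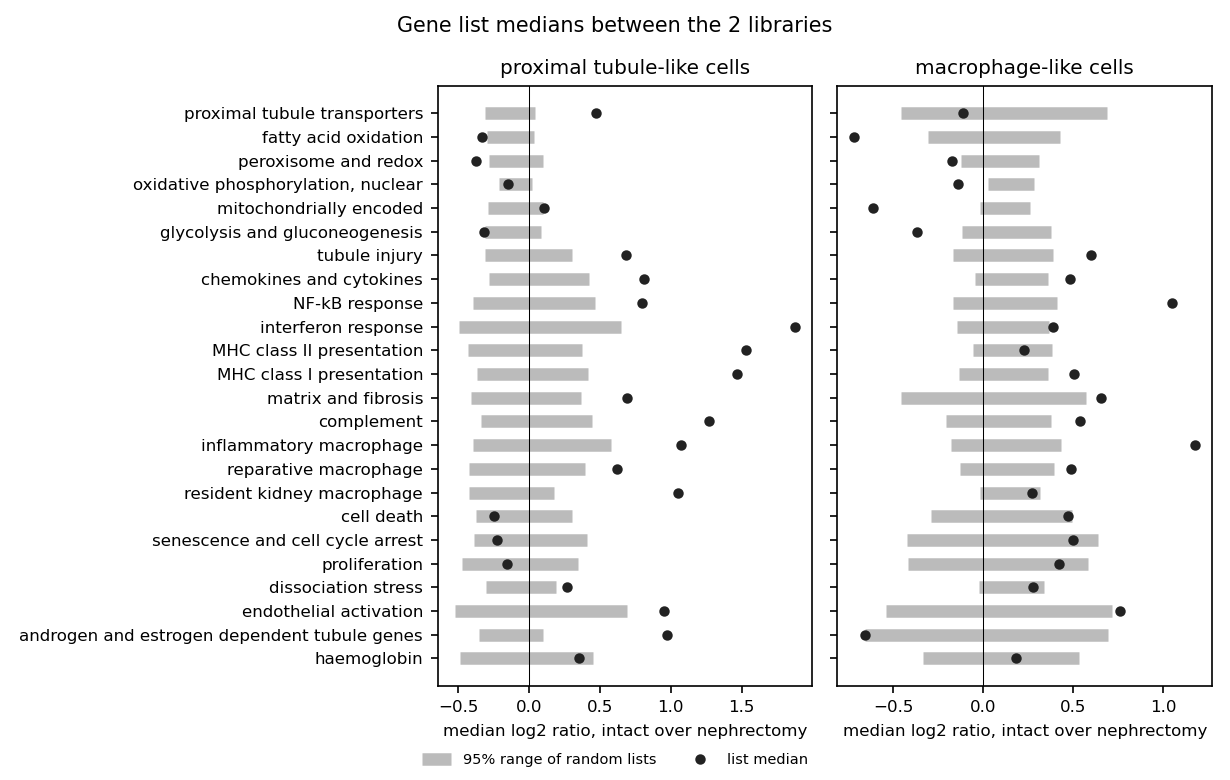
Median log2 ratio, intact over nephrectomy, of each fixed gene list (points) in proximal tubule-like and macrophage-like cells, with the 95% range of 10000 random lists of the same size and expression (grey bars). In proximal tubule-like cells the transporters were at 0.47 and fatty acid oxidation at -0.33, and in macrophage-like cells the inflammatory macrophage list was at 1.18.

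In injured tubule epithelium-like cells the genes of injury themselves were at like levels, and genes of class II presentation were higher in the intact library. Spp1 was at 11044 and 10905 CPM and Havcr1 at 403 and 445 CPM, and of 21 tubule injury genes measured 3 were higher, 1 was lower and 17 lay between (median 0.07, inside the random range). The markers that named this class, Spp1 and Havcr1 among them, are all members of that list. The like levels were thus partly set by the choice of cells and do not show that injury was alike. Cp, ceruloplasmin, was at 180 and 463 CPM, Tpm2, a tropomyosin, at 114 and 275 CPM and Flna, filamin A, at 150 and 310 CPM. Acta2, smooth muscle actin, was at 295 and 814 CPM, but of 12 matrix and fibrosis genes 5 were higher, 1 was lower and 6 lay between (median 0.27, inside the random range). Timm10b (96.2 and 228 CPM) and Sptbn1 (156 and 340 CPM) also met the rule. Aqp1, the water channel of the proximal tubule, was at 457 and 146 CPM. Gclm, a subunit of the enzyme that starts glutathione synthesis, was at 259 and 93.7 CPM, and Slc25a5, a mitochondrial ADP/ATP carrier, at 517 and 199 CPM. Ndufb5 (337 and 117 CPM) and Mrpl57 (223 and 82.0 CPM) were lower as well. Of 6 class II genes 5 were higher and 1 lay between (median 1.39), with Cd74 at 878 and 2290 CPM beside the macrophage gene C1qb at 60.2 and 129 CPM. Of 12 genes of glycolysis and gluconeogenesis 6 were lower and 6 lay between (median -0.47, 0.560th percentile), beside a tubule transcript, Kap, at 5323 and 4650 CPM. C3 was at 451 and 785 CPM, and Ccl2, a chemokine that draws monocytes, at 6.02 and 146 CPM on 1 and 25 corrected counts.

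Macrophage-like cells of the intact library held more transcripts of the chemokines Ccl8, Ccl7 and Cxcl9 and of genes of the inflammatory macrophage list. Ccl8 was at 415 and 1313 CPM (3.16-fold higher in the intact library), Ccl7 at 86.5 and 381 CPM (4.41-fold) and Cxcl9, which draws T cells, at 24.4 and 143 CPM (5.86-fold). The class was made of cluster 6, deep cells that formed 21.8% and 30.5% of it, and cluster 11, shallow cells that formed 78.2% and 69.5%. Each of the 12 genes named as higher was higher in both clusters. Ccl8 was at 987 and 2487 CPM in cluster 6 and at 220 and 648 CPM in cluster 11. The most abundant transcripts differed little: Cd74 was at 29276 and 34238 CPM and Apoe at 16070 and 19476 CPM.

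The other genes named as higher were Socs3, an inhibitor of cytokine signalling (167 and 486 CPM), Manf (39.5 and 119 CPM), Naaa, a lysosomal amidase (37.6 and 108 CPM), Slamf8 (43.2 and 122 CPM) and the zinc transporter Slc39a1 (35.7 and 101 CPM). Lyz1, a lysozyme with a close copy, was at 75.2 and 229 CPM, but 112 of its 131 corrected counts in the intact library lay in 7 cells. Others were vimentin, Vim (126 and 327 CPM), Anxa3 (43.2 and 112 CPM) and properdin, Cfp (73.3 and 180 CPM). Dnaja1, a co-chaperone (102 and 38.5 CPM), was lower. 26 further genes of the size needed were left out as free RNA, since another class held over 5 times as much. Proximal tubule transcripts in these cells were lower in the intact library: Kap was at 2965 and 1875 CPM, Pck1 at 180 and 21.0 CPM, and Gpx3 at 2202 and 1325 CPM. The metabolic lists lay low beside them: fatty acid oxidation had 10 of 14 members lower and 4 between (median -0.71) and mitochondrially encoded genes 10 of 13 lower (-0.61). Glycolysis and gluconeogenesis had 4 of 12 lower and 1 higher (-0.36), and peroxisome and redox genes 4 of 14 lower (-0.17). The former lay inside the random range in cluster 6 (-0.08) and the latter in cluster 11 (0.02). Nuclear genes of oxidative phosphorylation had 2 of 32 lower and 30 between (-0.14, below the random range). Genes under androgen or estrogen control had 2 of 3 lower (-0.65, at the lower end of the range). Proximal tubule transporters had 1 of 6 higher and 1 lower (-0.11, inside the range).

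Of 13 inflammatory macrophage genes 8 were higher and 5 lay between, with a median of 1.18 (100th percentile): Ccl2 was at 150 and 346 CPM and Ccr2, a receptor of blood monocytes, at 276 and 456 CPM. Within the single clusters both differed by less. Ccr2 was at 744 and 1040 CPM in cluster 6 and at 116 and 126 CPM in cluster 11. Ccl2 was at 471 and 852 CPM in cluster 6 and at 40.4 and 60.2 CPM in cluster 11. Ly6c2, at 3.76 and 47.2 CPM, was carried by 1 cell that held 24 of its 27 corrected counts in the intact library. Il1b was at 400 and 533 CPM (1326 and 1263 CPM in cluster 6, 83.3 and 120 CPM in cluster 11), Ccl3 at 318 and 311 CPM and Ccl4 at 462 and 463 CPM. Of 14 NF-kB response genes 9 were higher and 5 lay between (1.05, 100th percentile), with Ier3 at 84.6 and 283 CPM, Nfkb2 at 11.3 and 64.7 CPM and Cd83 at 124 and 252 CPM. This list lay inside the random range in the deep cluster 6 (median 0.25, 4 of 10 higher, 1 lower) and above it in the shallow cluster 11 (1.88). Of 18 chemokines and cytokines 8 were higher and 10 lay between (0.48), with Ccl5 at 130 and 339 CPM and Ccl12 at 541 and 638 CPM. This list shares members with the inflammatory list, among them Ccl2, Ccl3, Ccl4 and Il1b, so the lists are not independent. Of 16 reparative macrophage genes 7 were higher, 1 was lower and 8 lay between (0.49), with Fabp5 at 77.1 and 171 CPM and Spp1 at 333 and 449 CPM. The list was inside the random range in cluster 6 (0.27). Members of both the inflammatory and the reparative list stood higher. Class II genes (1 of 9 higher, 8 between, 0.23) and resident kidney macrophage genes (0 of 14, 0.27) lay inside the random range. H2-Eb1 was at 9821 and 11207 CPM. Median-ratio scaling in place of CPM shifted the median of all genes by -0.13 in this class. The medians were smaller in cells with a depth index of at least 1: 0.79 for inflammatory macrophage, 0.61 for NF-kB response, 0.14 for chemokine and 0.25 for reparative macrophage genes. The inflammatory list was at 0.47 and the NF-kB list at 0.50 over members with at least 100 corrected counts. The chemokine list was at 0.22 with each cluster weighing alike and 1.03 with cluster 17 added. With cluster 10 added the inflammatory list was at 0.63, the NF-kB list at 0.73 and the chemokine list at 0.33.

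The remaining lists in macrophage-like cells lay above or inside the random range. Complement genes (4 of 9 higher, 5 between, 0.54) included C3 at 13.2 and 122 CPM and C1qa at 3948 and 5345 CPM. MHC class I genes (4 of 13 higher, 9 between, 0.50) included H2-D1 at 1348 and 1865 CPM. Interferon response genes (8 of 18 higher, 1 lower, 0.39) had medians of 0.01 and 0.21 within clusters 6 and 11. Tubule injury genes (8 of 14 higher, 1 lower, 0.60) included Tmsb10 at 540 and 876 CPM. Matrix and fibrosis genes (4 of 7 higher, 3 between, 0.66) included Fn1 at 15.04 and 52.4 CPM. The matrix median was -0.05 over members with at least 1 corrected count. Endothelial activation genes (2 of 3 higher, 0.76) lay above the random range. Cell death (5 of 11 higher, 0.47), senescence (2 of 5 higher, 1 lower, 0.50), proliferation (1 of 5 higher, 0.42), dissociation stress (6 of 17 higher, 1 lower, 0.27) and haemoglobin genes (0 of 4, 0.18) lay inside it. Fos, an early response gene of the stress list, was at 1079 and 1594 CPM.

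T-like cells of the intact library held more transcripts of the inhibitory receptor Pdcd1, and a few of them held many of Il17a, the cytokine interleukin 17A. Pdcd1 was at 24.02 and 151 CPM, on 3 and 54 corrected counts in 3 of 94 and 30 of 252 cells. Il17a was at 16.01 and 251 CPM, on 2 and 90 corrected counts in 2 and 17 cells, and in cluster 23 the share of cells with it was alike (3.92% and 4.35%). Of 18 measured genes of T cell activation and effector function 7 were higher, 1 was lower and 10 lay between (median 0.49, 99.8th percentile): Ctla4 was at 80.1 and 237 CPM, Foxp3, which defines regulatory T cells, at 24.02 and 106 CPM, and Ifng at 48.0 and 101 CPM. Ccl5 was at 2866 and 2341 CPM and Nkg7 at 729 and 707 CPM. The class was made of cluster 16, shallow cells that formed 45.7% and 27.0% of it, and cluster 23, which formed 54.3% and 73.0%. The median of the list was 0.13 and 0.09 within them. G3bp2, Rsrc2 and Vmp1 were the other genes named as higher, with G3bp2 at 32.0 and 131 CPM. Nme1 (344 and 131 CPM), Ikbkb (232 and 97.8 CPM), Cox5a (504 and 218 CPM), the phosphatase Dusp2 (504 and 229 CPM) and Higd1a (176 and 86.6 CPM) were lower. Tubule RNA was lower in the intact T-like cells, with Gpx3 at 1569 and 360 CPM. So were peroxisome and redox genes (7 of 11 lower, 2 higher, -1.15), mitochondrially encoded genes (11 of 12, -0.88) and haemoglobin genes (4 of 4, -1.23). The peroxisome and mitochondrial lists lay below the random range in both clusters, with medians between -0.89 and -0.65. The haemoglobin list did so in the shallow cluster 16 (3 of 3 lower, -2.18) but not in cluster 23 (0 of 3 lower, -0.08).

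Neutrophil-like cells of the intact library had more Tnf, at 37.9 and 369 CPM on 3 and 47 corrected counts, and more of the NF-kB inhibitor Nfkbia, at 1338 and 3556 CPM. Zfp36, which destabilises cytokine mRNA (1099 and 2606 CPM), Dusp2 (202 and 706 CPM) and Clec5a (126 and 361 CPM) were also named as higher. Retnlg (1427 and 408 CPM), the protease inhibitor Slpi (3940 and 1680 CPM) and Id1 (429 and 212 CPM) were lower. Il1b was at 7147 and 11507 CPM, and of 12 chemokines and cytokines 8 were higher, 1 was lower and 3 lay between (median 0.72, above the random range), with Cxcl2 at 7741 and 7049 CPM. Of 17 dissociation stress genes, which include early response genes such as Fos (1705 and 3093 CPM), 9 were higher, 1 was lower and 7 lay between (0.63). S100a8, a major neutrophil transcript, was at 42694 and 43391 CPM. Mitochondrially encoded genes (11 of 12 lower, -0.94) and peroxisome and redox genes (4 of 10 lower, -0.21) lay below the random range. Tubule RNA was lower beside them, with Kap at 1301 and 549.5 CPM and Gpx3 at 1250 and 369 CPM.

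In endothelial-like cells the genes of endothelial activation were at like levels, while class II genes as a list were higher and mitochondrially encoded genes lower in the intact library. Of 17 endothelial activation genes 1 was higher, 1 was lower and 15 lay between (median 0.04, inside the random range), with Plvap, a component of vessel diaphragms, at 2702 and 3036 CPM. Plvap, Kdr, Flt1, Emcn, Ehd3 and Eng of this list are also markers that named the class. The like levels were thus partly set by the choice of cells and do not show that activation was alike. Plat, tissue plasminogen activator, was at 144 and 327 CPM and Pdia3, a chaperone of the endoplasmic reticulum, at 130 and 315 CPM. Clk1 (85.3 and 218 CPM), Anp32b and Erdr1 (98.7 and 244 CPM each) were also named as higher, with Snrpe (260 and 128 CPM) as lower. Mgp, an inhibitor of calcification, was at 238 and 1200 CPM. Class II genes (4 of 5 higher, 1.03) stood above the random range, beside C1qa at 67.3 and 141 CPM. Mitochondrially encoded genes (6 of 12 lower, -0.58), peroxisome and redox genes (6 of 10 lower, 1 higher, -0.63), fatty acid oxidation genes (5 of 11 lower, 1 higher, -0.53) and nuclear genes of oxidative phosphorylation (2 of 32 lower, 1 higher, -0.12) lay below it. Tubule RNA was lower beside them, with Gpx3 at 1755 and 565 CPM.

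Over all cells together, Cd3g, Cd3e and Lat, which encode parts of the T cell receptor complex and its adaptor, were higher in the intact library. Gsta2, Pck1, Acaa1b and Ak4 were lower, as they were within proximal tubule-like cells. Cd3g was at 35.1 and 278 CPM, Xcl1, a chemokine of NK and T cells, at 8.52 and 120 CPM, and Gimap3 at 20.9 and 137 CPM, while Calb1, a gene of the distal convoluted tubule, was at 145 and 19.4 CPM. Of 24 genes of T cell activation and effector function 23 were higher (median 1.89), and of 26 fatty acid oxidation genes 24 were lower (-1.08). Values over all cells take in the class shares: the same lists were at 0.49 within T-like cells and at -0.33 within proximal tubule-like cells, where 7 of 26 were lower. Median-ratio scaling shifted the median of all genes by -0.14 over all cells, -0.15 in T-like, -0.17 in neutrophil-like and -0.11 in endothelial-like cells.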

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

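Of the 43 alternatives, 26 were fixed before the data were examined and 17 were chosen after seeing them. Share ratios (7 results) stayed within the bounds of the main value in 58 cases, moved in 17 and reversed in 1; list medians (48 results) in 388, 141 and 3; named genes (38 results) in 414, 18 and 0; shares of cells with a value (24 results) in 55, 17 and 0. Part of this tally was fixed in advance. Removing the 1 and 3 cells marked by scrublet could move almost nothing, and it stayed in all 7, 48, 38 and 24 of its cases. Median-ratio scaling shifted all genes of a class alike, by 0.09 in proximal tubule-like and -0.13 in macrophage-like cells. That is less than the bound for a named gene, so all 38 stayed. These cases say little about robustness. No paired analysis was possible because each group has 1 library. The cause of the moves given here was not tested.

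Subtracting library means before clustering gave a proximal tubule-like share ratio of 0.486, and clusters from the deposited residuals (added) 0.493. The subtraction set the libraries apart: a proximal tubule-like cluster held 0 and 493 cells and a macrophage-like cluster 2 and 373 cells. It is therefore a weak check. In cells with at least 1000 corrected counts and under 25% mitochondrial counts the proximal tubule-like ratio was 0.348 and the injured tubule ratio 1.21. As a share within leukocytes or within the other cells, the ratios were 0.628 for proximal tubule-like, 2.89 for injured tubule, 1.82 for endothelial-like, 1.93 for T-like, 1.61 for NK-like, 1.15 for neutrophil-like and 0.776 for macrophage-like cells, the last reversed. The highest marker score gave 2.06 for NK-like and 1.71 for neutrophil-like cells. A depth index under 1 (added) gave 0.59 for proximal tubule-like and 2.51 for T-like cells.

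In cells with a depth index of at least 1 (added) the injured tubule ratio was 1.06 and the macrophage-like ratio 2.28. In such proximal tubule-like cells the median of tubule injury was 0.21 and of androgen- or estrogen-dependent genes 1.10. In such macrophage-like cells the medians were 0.14 for chemokines, 0.61 for NF-kB response and 0.0463 for class II. They were 0.79 for inflammatory macrophage and 0.25 for reparative macrophage genes. With each cluster weighing alike (added), proximal tubule-like medians were 0.15 for transporters, -0.23 for fatty acid oxidation and 0.49 for tubule injury. They were 0.42 for androgen- or estrogen-dependent genes and -0.28 for mitochondrially encoded genes, the last reversed. By the same weighing macrophage-like medians were 0.22 for chemokines, 0.75 for NF-kB response, 0.0562 for class II and 0.82 for inflammatory macrophage genes. With cluster 17 added to the macrophage-like cells (added) the chemokine median was 1.03. With cluster 10 added (added) the macrophage-like share ratio was 1.56, and the medians were 0.33 for chemokines, 0.73 for NF-kB response and 0.63 for inflammatory macrophage genes.

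Median-ratio scaling gave -0.23 for fatty acid oxidation in proximal tubule-like cells, and 0.36 for chemokines and 0.0901 for class II in macrophage-like cells. With injured tubule-like cells joined to the proximal tubule-like cells, the medians were 0.19 for transporters, -0.51 for fatty acid oxidation and 1.32 for tubule injury. They were 1.94 for class II and 0.59 for androgen- or estrogen-dependent genes. A pseudocount of 20 gave 0.35 for transporters and 0.48 for tubule injury in proximal tubule-like cells and 0.94 for inflammatory macrophage genes in macrophage-like cells. With members of at least 1 corrected count, tubule injury was at 0.42 and class II at 1.21 in proximal tubule-like cells, and NF-kB response at 0.87, inflammatory macrophage genes at 0.62 and matrix genes at -0.0462 (reversed) in macrophage-like cells. With members of at least 100 corrected counts, transporters were at 0.36, tubule injury at 0.0917 and dissociation stress at -0.00840 (reversed) in proximal tubule-like cells, and NF-kB response at 0.50 and inflammatory macrophage genes at 0.47 in macrophage-like cells.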

Other observations

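The sources of the inflammatory signals differed by cell class, seen after the values had been printed. Il1b and Csf1, the macrophage growth factor, were highest in neutrophil-like cells, with Csf1 at 265 and 447 CPM. Il34, the other ligand of the same receptor, was highest in injured tubule epithelium-like cells (72.2 and 105 CPM) and was at 15.6 and 15.8 CPM in proximal tubule-like cells. Ccl8, Ccl7 and Ccl12 were highest in macrophage-like cells, and Ccl5 in NK-like cells (21650 and 24870 CPM). NK-like cells of the intact library held more Xcl1, which draws cross-presenting dendritic cells (647 and 2775 CPM), and more of the cytotoxic granule gene Gzmb (379 and 1291 CPM), while Gzma was at 3836 and 2689 CPM, in 29 and 65 cells. Il17a was found in the T-like class above all: 2 of 51 and 8 of 184 cells of cluster 23 and 0 of 43 and 9 of 68 cells of cluster 16 held it.

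The unnamed cluster 17 was 1.06% and 3.87% of the cells, and the clustering at the higher resolution split it, which was seen after its values. Monocyte-like cells in it, with Plac8 at 6684 and 6620 CPM, were 16 and 15 cells (0.445% and 0.735%), and none of them held Retnla or Mmp12. Il1b was at 623 and 2741 CPM in them, in 6 and 12 cells. The other 22 and 64 cells (0.612% and 3.14%) held Retnla, a gene of alternative activation, at 129.9 and 2052 CPM (in 1 and 15 cells), Mmp12 at 682 and 902 CPM and Cxcl2 at 325 and 1285 CPM (in 3 and 15 cells), while Il1b was at 3313 and 2277 CPM. Cluster 12 held genes of migrating dendritic cells, with Fscn1 at 2083 and 3202 CPM, Ccl22 at 1250 and 1515 CPM and the lymph node homing receptor Ccr7 at 885 and 1573 CPM, and was 0.445% and 1.37% of the cells.

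The larger leukocyte share in the intact library was weighed first; all tests given here were chosen only after the result was seen. A lower share of tubule cells alone would raise every other class alike, but the T-like to endothelial-like ratio of cells differed 3.88-fold (2.73 to 5.51) between the libraries, which argues against it as the only cause. T-like cells had the largest difference, but the ratio was also 3.24 (1.92 to 5.54) for NK-like, 2.31 (1.49 to 3.60) for neutrophil-like and 1.56 (1.18 to 2.07) for macrophage-like cells; for B-like cells it was 1.09 (0.598 to 1.95), which that explanation allows. A difference in depth could hide leukocytes in 1 library, but the leukocyte ratio was 1.83 in cells with a depth index under 1 and 3.21 in the others. A larger leukocyte infiltrate in kidneys left beside an intact kidney may be the cause, and was not tested, as animal, library and operation differ together.

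Class II genes were higher in proximal tubule-like cells of the intact library. Free RNA from leukocytes could account for it. The class II median exceeded that of macrophage markers in the same cells by only 0.23, with a spread of 0.325 for random lists. Cd74 itself was at 234 and 760 CPM in them. In T-like cells it was at 712 and 740 CPM, in neutrophil-like cells 644 and 848 CPM and in stromal-like cells 458 and 2058 CPM. The background thus did not differ alike in all classes, and free RNA is not settled as the cause. Doublets could put many Cd74 counts into few cells, and without the 3 and 1 cells with at least 10 counts the median was 1.56. This cut cannot decide. The median depth index was 2.79 and 1.86 in proximal tubule-like cells but 0.414 and 0.440 in macrophage-like cells. A doublet could thus hold only a small part of the macrophage-like median of 27 and 36 Cd74 counts and fall below the cut. Induction of class II genes in tubule cells of the intact library remains possible and would need protein staining.

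In proximal tubule-like cells, genes under androgen or estrogen control and transporters were higher and fatty acid oxidation genes lower in the intact library. A different mix of clusters could account for the transporters, whose median was 0.15 with each cluster weighing alike. It accounts less for genes under androgen or estrogen control, whose median (0.42) stayed outside the random range. Among the single clusters, though, only clusters 5 and 7 put this list outside that range. Fatty acid oxidation was at -0.23 by the same weighing, below the random range, which argues against the mix as the only cause there, although of the 6 clusters only cluster 8 (-0.68) lay outside the range by itself. The differences were not confined to shallow cells. Medians in cells with a depth index of at least 1 were 1.10 for androgen- or estrogen-dependent genes, 0.52 for transporters and -0.41 for fatty acid oxidation. These cells were not matched on depth between the libraries, and their clusters were pooled. The values therefore cannot decide whether depth played a part. A hormonal difference between the animals may contribute and was not tested.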
